A study of Mus musculus with 2 samples.

How the data were processed

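Total RNA of mouse heart was labelled with Cy3 and hybridised to 1-colour Agilent expression arrays, 1 array for a control heart of C57BL6 background and 1 for a heart of the transgenic WRN-K577M line. Groups were taken from the genotype given in the labels. Both sample titles also carry the letters ND, whose meaning is not given in the sources used here, and whether a sample was 1 heart or a pool is not given either. Both arrays lay on the same slide and in the same scan, so no slide or scan date separates them. The spot files are scanner output, and the intensity values in them were made with Agilent Feature Extraction 11.5.1.1, per the file headers and the submitters' processing notes. The processed signal in those files is a background-subtracted and detrended intensity that was not scaled between arrays, per the file headers. The median spot and local background intensity are given unprocessed, and other columns hold the software's 0 or 1 flags for outliers, saturation and signal well above background, per the file headers. The deposited series matrix holds intensity on a linear scale: each column is the processed signal of the same array times a single factor, 4.12 for the control and 4.86 for the WRN-K577M array, which was checked over all spots. Its column medians are 79.5 and 79.0, and it is neither log-transformed nor centred by gene. How the authors chose the factors is not given in the sources used here.

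From the processed signal, control spots were left out, and so were 257 spots that were outliers on either array. No spot was saturated. The log2 processed signal minus the array's 75th percentile over non-control spots was the main level, and spots of a probe were averaged. The 75th percentile was 256 in the control and 210 in the WRN-K577M array, the mean local background 42.3 and 44.1, and the slope of the spike-in series 0.977 and 0.965. The files give probe names and accessions but no gene names in the columns used, so RefSeq accessions, versions removed, were matched to a table of the GRCm38.p6 assembly. Of 23871 RefSeq accessions, 22544 matched, which names 28330 probes (50.9%) with 1 symbol each, none with several, and leaves 27350 probes unnamed here. The array's design is annotated on the earlier build mm9, per the file headers, so no coordinates are given and the table served for names and gene order only. A gene took the value of its brightest probe that was well above background on both arrays. Of 21368 named genes, 14003 were measured in this way, 3650 by more than 1 probe, and for 90 of these the probes' log2 ratios differed by 1 or more. A gene well above background on 1 array by any probe and on the other by none has a bound: its level on the brighter array against the higher of its own level on the other array and the lowest level there of a probe well above background (-4.73 for the control and -4.42 for the WRN-K577M array). A total of 6412 genes were not well above background on either array.

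With 1 array per group no test between genotypes can be made, and the number of arrays limits the precision. Genes are therefore described by their ratio, counted at 2-fold, and set beside the spread between spots of the same probe and the software's own error estimate, both of which cover measurement only. The 40 gene lists, the sex-linked and strain marker genes and the rule for named genes were fixed before the data were examined. The rule names the probes of Wrn, the 10 measured genes with the largest log2 ratio in each direction (without predicted or clone names, all measured probes on one side), the 3 largest bounds in each direction under the same exclusion of names, up to 4 members with the largest absolute ratio of each list discussed, and the check genes. Some genes that the rule names are not reported here. Genes named beyond it, such as near-equal members of a list, were chosen after their values were seen. A list's median was placed among 10000 random lists of the same size drawn from measured genes in 20 bins of mean level. The fatty acid oxidation and interferon lists lie so near the 97.5th percentile that other random draws place them on either side of it.

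The alternatives were normexp background correction with an offset of 50, quantile normalization, cyclic loess, the 75th percentile of detected probes, the median of all probes, no filter and a stricter filter on dim probes, the mean of a gene's probes, the deposited matrix, and thresholds of 1.5-fold and 3-fold. Normexp was planned on the mean spot signal and was run on the median spot signal, the raw signal used here. A filter on the mean level of both arrays, and counts without members of other-tissue and stromal lists, were added after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, R 4.3.3 with limma 3.58.1, and matplotlib 3.10.9. The counting and the list percentiles were tested on simulated data for this comparison with the measured spot error and 14003 genes: 49 of 50 genes made 2.5-fold different and all 50 made 4-fold or 8-fold different were counted at 2-fold, none of 50 at 1.5-fold was and 0 unchanged genes were, all 10 lists shifted by 0.3 lay above the central 95% of random lists, and 3 of 100 unshifted lists lay outside it. Every simulated gene had the same ratio SD of 0.13, against an SD of 0.52 over the measured genes. At that error no unchanged gene could be expected at 2-fold. The simulation checks the calculation and gives no rate of false counts for these arrays.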

Results

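Total RNA from mouse heart was measured in 2 samples, 1 per group, each on its own 1-colour Agilent expression array. The control sample was of C57BL6 background. The other came from a transgenic line of that background that carries WRN-K577M, a form of the WRN protein with a substitution in its helicase domain, under the ubiquitously active CAG promoter. WRN is a DNA helicase of the RecQ family whose loss causes Werner syndrome, a disease of premature ageing. The comparison of the 2 samples asks which signalling accompanies remodelling of the heart in this line. Each array held 55681 probes that are not controls, and 55.2% of the probes on the control array and 52.9% on the WRN-K577M array were well above background. A total of 14003 named genes had a probe well above background on both arrays and are called measured here. Levels are log2 signals relative to the 75th percentile of the array, and a log2 ratio is the WRN-K577M level minus the control level.

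The WRN-K577M heart had higher levels of some cardiomyocyte stress genes, with others of the same list such as Nppa (log2 ratio -1.06) lower. Levels of several genes for the defence against oxidants were higher. Lung genes and many, though not all, atrial, fat, blood cell and connective tissue genes had lower levels. Of the measured members, 5 of 17 atrial and 8 of 23 adipocyte markers lay above 0. The B cell median was 0.019 after normexp background correction. Myh7, the slow beta-myosin heavy chain, had the highest log2 ratio of all measured genes, 3.91 (15.1-fold), with a level of 5.66 in the control and 9.57 in the WRN-K577M heart. Nppb, the precursor of brain natriuretic peptide, was higher by a log2 ratio of 2.26, Ccn2, a matricellular growth factor also called Ctgf, by 2.69, and Hmox1, heme oxygenase, by 2.45. The largest differences lay in the other direction. Sln, the atrial calcium pump regulator sarcolipin, was 678-fold lower in the WRN-K577M heart, and the atrial myosin light chains Myl7 and Myl4 were 168-fold and 139-fold lower. Sftpc, a surfactant protein made by lung epithelium, had a level of 5.96 in the control and was not well above background in the WRN-K577M heart, at least 1336-fold lower.

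With 1 array per group these differences have no replicate check, no p-value is given, and differences between genotypes are not separated from other differences between the 2 samples. Measurement error within an array was small: 269 probes printed at 10 spots each gave a log2 ratio that varied between spots with an SD of 0.13, so that 2 SD make 1.19-fold. The software's own error of the log2 ratio lay between 0.20 and 0.34 for the 20 genes with the largest ratios.

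Of the 14003 measured genes, 271 were at least 2-fold higher and 484 at least 2-fold lower in the WRN-K577M heart, together 5.39%. At 3-fold the numbers were 63 and 154. The SD of the log2 ratio over genes was 0.52 and its median 0.020, 84.1% of the genes lay within 1.5-fold, and levels on the arrays correlated across genes with a Pearson r of 0.983, genes not being independent replicates. A further 209 genes were well above background on the WRN-K577M array only and 740 on the control array only, and for these the ratio is a bound. Of them, 70 were at least 2-fold higher and 138 at least 2-fold lower. After background correction by normexp, which adds a constant to every signal, the numbers of measured genes at least 2-fold different were 115 higher and 197 lower.

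**Figure D1:**
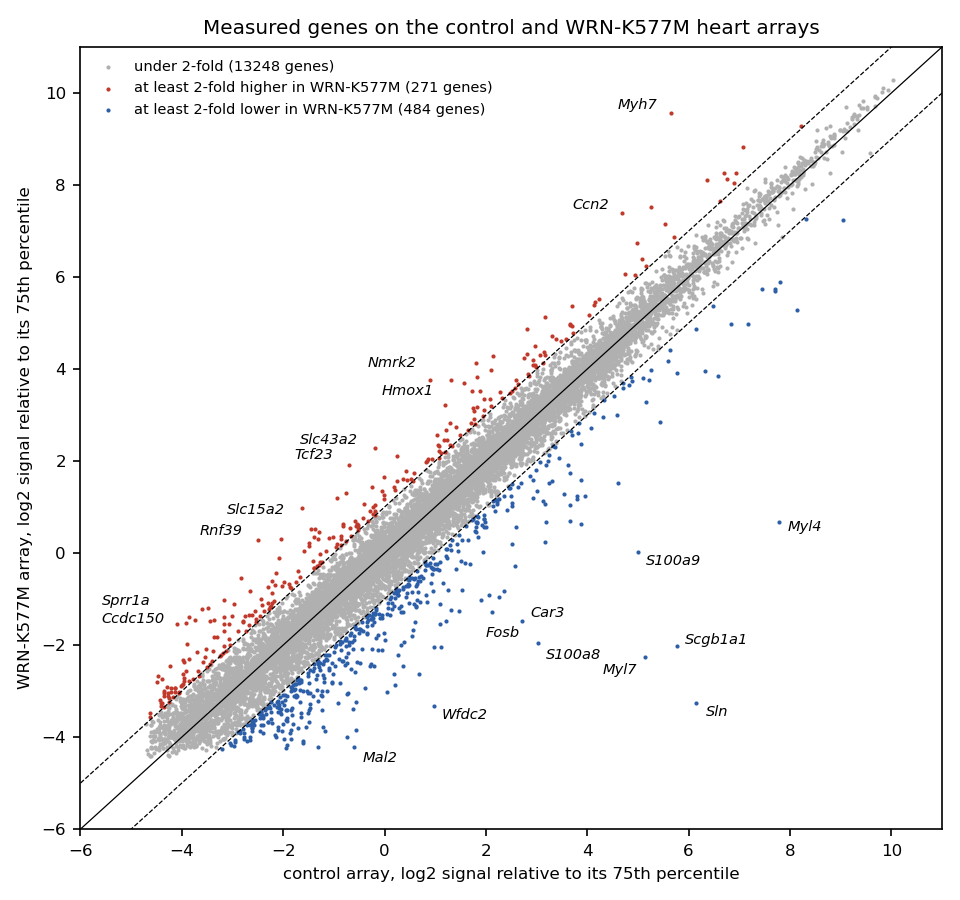
Level of each of the 14003 measured genes on the control array (x axis) and the WRN-K577M array (y axis), as log2 signal relative to the array's 75th percentile. The solid line marks equal levels and the dashed lines a 2-fold difference. Red points are the 271 genes at least 2-fold higher and blue points the 484 at least 2-fold lower in the WRN-K577M heart, and the 10 genes with the largest ratio in each direction are named.

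The mouse Wrn gene was read by 2 probes that differed. One was well above background on both arrays and near equal, with levels of -3.02 in the control and -3.23 in the WRN-K577M heart. The other was not well above background in the control and had a level of -3.96 in the WRN-K577M heart, at least 1.71-fold higher. The probes were designed on mouse transcripts, and whether they detect the transgene's message is not known, so they do not check the label. The Y-linked genes Ddx3y (log2 ratio 0.054) and Eif2s3y (0.11) were well above background and near equal in the control and WRN-K577M hearts, and Xist, the RNA of the inactive X chromosome, was not well above background in either. Among the genes often used to tell C57BL6 substrains and related strains apart, Ide had a log2 ratio of -0.23, Entpd4 of -0.13, Glo1 of -0.077 and Klra8 of -0.15, the probes of Wdfy1 differed from one another (-0.19 to 0.91), and no probe was named Nnt here. Hc, the complement C5 gene, had a level of 0.60 in the control and was not well above background in the WRN-K577M heart, at least 32.3-fold lower. Lung markers were lower in the same heart too, so Hc does not settle whether the samples differ in strain background.

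The 10 measured genes with the largest ratio in each direction, among those with an established name and with all their probes on one side, were as follows. Above Hmox1 and below Myh7 stood Nmrk2, a nicotinamide riboside kinase of muscle, with a log2 ratio of 2.87, Rnf39 with 2.79, Ccn2, Tcf23, a transcription factor, with 2.62, Slc15a2, a peptide transporter, with 2.62, Sprr1a with 2.55, Slc43a2, an amino acid transporter, with 2.46, and Ccdc150 with 2.46. After normexp the ratios of the dim genes Sprr1a and Ccdc150 were 0.96 and 0.94. In the other direction, after Sln (-9.41), stood Scgb1a1, the secretoglobin of airway club cells (-7.78), Myl7 (-7.39), Myl4 (-7.12), the neutrophil calgranulins S100a9 (-4.98) and S100a8 (-4.98), Wfdc2, an epithelial secreted protein (-4.29), Car3, a carbonic anhydrase abundant in fat (-4.20), Mal2 (-3.62) and the immediate-early gene Fosb (-3.40). The largest bounds, with predicted and clone names left out, were those of Rln1, relaxin (at least 17.1-fold higher), Rnase1 (11.2-fold) and Dnaic2 (6.78-fold), and of the surfactant proteins Sftpc, Sftpd (at least 130-fold lower) and Sftpb (113-fold).

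Gene lists were fixed before the data were examined. The median log2 ratio of each list is given with its percentile among 10000 random lists of as many measured genes matched on mean level, which describes these arrays and is not a test between genotypes. Of the 40 lists, 3 lay above and 18 below the central 95% of the random lists, where 2 would by chance if the lists were independent. In many lists fewer members were at least 2-fold different after normexp or with the stricter filter on dim probes.

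**Figure D2:**
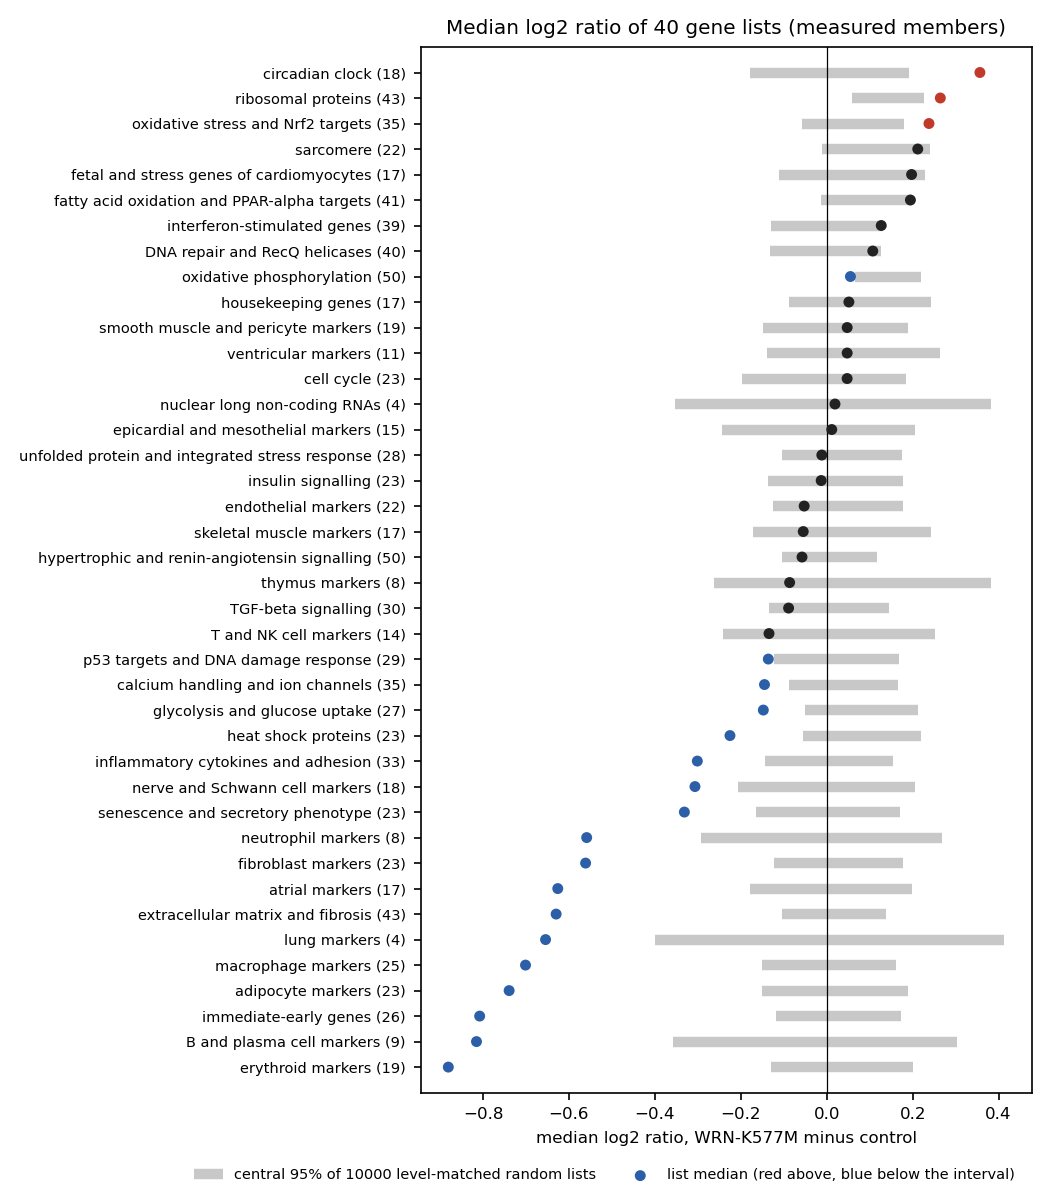
Median log2 ratio (x axis, WRN-K577M minus control) of the measured members of 40 gene lists, with the number of members in parentheses. Grey bars span the central 95% of 10000 level-matched random lists. The erythroid list, at -0.88, had the lowest median and the circadian clock list, at 0.36, the highest.

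Among 17 fetal and stress genes of cardiomyocytes, 6 were at least 2-fold higher and 3 at least 2-fold lower. The higher ones were Myh7, Nppb, the calcineurin regulator Rcan1 (1.49), the stress cytokine Gdf15 (1.42), the mechanosensitive titin-bound protein Ankrd1 (1.33) and Xirp1 (1.12). The lower ones were Myl4, the smooth muscle calponin Cnn1 (-1.26) and Nppa (-1.06), the precursor of atrial natriuretic peptide. The list's median was 0.20 (percentile 93.7), inside the central 95% of the random lists. Myl4 and Nppa also belong to the atrial list, 8 of whose 17 measured members were at least 2-fold lower. Of 22 sarcomere genes, 19 had a ratio above 0 with a median of 0.21 (percentile 92.2), and Myom2, myomesin of the M-band, was the sole one at least 2-fold higher (1.06). With quantile normalization the sarcomere median was 0.017 (percentile 40.9) and Myom2 had a ratio of 0.94, and with cyclic loess the values were 0.044 and 0.90. Ventricular markers were near equal, with a median of 0.048 over 11 genes, a lower quartile of -0.29 and an upper quartile of 0.22. That median was -0.090 after normexp, -0.055 with quantile normalization, -0.081 with cyclic loess and -0.0031 with the deposited matrix.

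Of 43 genes of the extracellular matrix and fibrosis list, 35 had a ratio below 0 and the median was -0.63, below all random lists. The 13 that were at least 2-fold lower included the fibrillar collagens Col3a1 (-2.29) and Col1a1 (-1.73), Col14a1 (-1.90) and Comp (-1.74). Ccn2 and Thbs4, a thrombospondin (1.21), were at least 2-fold higher. The fibroblast markers had a median of -0.56 over 23 genes, 5 of them at least 2-fold lower, led by Mfap4 (-2.04), Pi16 (-1.86), Lum (-1.51) and Clec3b (-1.40), while Dcn, decorin, had a ratio of -0.059. Lung and fat markers were lower in the same heart, the surfactant gene Sftpc at least 1336-fold. Of 30 genes of TGF-beta signalling, Tgfb2 (1.54) was among those at least 2-fold higher and Ltbp2 (-1.23) was at least 2-fold lower, with a median of -0.089 (percentile 8.17).

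Hypertrophic and renin-angiotensin signalling (50 genes, median -0.058, percentile 12.3) had 3 members at least 2-fold different: the p38 kinase activator Map2k6 (-1.36), Igf1r (1.30) and Prkcb (-1.11). In the insulin signalling list (23 genes, median -0.013, percentile 32.7) it was Irs2 alone, with 1.51. Genes of calcium handling and ion channels had a median of -0.14 over 35 genes (percentile 0.31). Its 4 members at least 2-fold lower were Sln, the potassium channel Kcnq1 (-1.73), the connexin of atrial and conducting tissue Gja5 (-1.31) and Cacnb2 (-1.07). Sln and Gja5 are also atrial markers. The cardiac calcium pump Atp2a2 (0.13), its inhibitor Pln (0.048) and the release channel Ryr2, with levels of 5.40 on both arrays, were near equal.

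The list of oxidative stress and Nrf2 targets had a median of 0.24 over 35 genes (percentile 99.9), and 25 of them were above 0. That median was 0.13 with cyclic loess (percentile 99.5). Hmox1, the metallothionein Mt2 (1.75), the glutathione synthesis subunit Gclm (1.41), Srxn1 (1.12) and Txnrd1 (1.00) were at least 2-fold higher, and the NADPH oxidase Nox4 (-1.32) at least 2-fold lower. Under most alternatives 4 rather than 5 members were at least 2-fold higher, and none was as much lower after normexp or with the stricter filter. The p53 target list had a median of -0.14 over 29 genes (percentile 1.66). Cdkn1a, the p53-induced cell cycle inhibitor, had a ratio of -0.54 and Plk3 of -1.18, and the list lay inside the central 95% after normexp, quantile normalization and cyclic loess. DNA repair and RecQ helicase genes had a median of 0.11 over 40 genes (percentile 94.8) with none at least 2-fold different, led by Rad52 (0.83) and Fen1 (0.55). The senescence and secretory list had a median of -0.33 over 23 genes (percentile 0.020), and of -0.13 with the stricter filter on dim probes. Macrophage markers, whose cells express some of these cytokines, were lower in the same heart (median -0.70), and so were lung markers. In the senescence list, Igfbp2 (-2.25), Il6 (-1.62), Icam1 (-1.34) and Cxcl1 (-1.27) were at least 2-fold lower. Gdf15 was among those at least 2-fold higher, and Cdkn2a, the gene of p16, had a ratio of -0.58. After normexp and with the stricter filter 1 member of the list was at least 2-fold lower, not 4.

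Fatty acid oxidation and PPAR-alpha targets had 5 of 41 members at least 2-fold higher and none as much lower: Angptl4, a lipoprotein lipase inhibitor (2.07), Pdk4, which limits pyruvate oxidation (1.56), the lipid droplet protein Plin2 (1.25), Acot2 (1.23) and Acot1 (1.08). The median was 0.19 (percentile 97.4, just inside the central 95%, and 98.9 after normexp), and Fgf21 was well above background in the WRN-K577M heart only, at least 3.18-fold higher. Glycolysis genes had a median of -0.15 over 27 genes (percentile 0.090) with none at least 2-fold different. Oxidative phosphorylation genes had a median of 0.055 over 50 genes, low for genes of their brightness (percentile 1.39) and with none at least 2-fold different, and its sign turned after normexp (-0.033), quantile normalization (-0.060) and cyclic loess (-0.088). Of 43 ribosomal protein genes, 42 were above 0, with a median of 0.26 (percentile 99.9) that was 0.13 with cyclic loess.

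Immediate-early genes had a median of -0.81 over 26 genes, below all random lists, with 10 at least 2-fold lower. These 10 included Fosb, Fos (-2.57), Nr4a1 (-1.85) and Nr4a2 (-1.46), and Myc (1.23) was higher. With the stricter filter on dim probes the median was -0.31 over 19 genes, 5 of them at least 2-fold lower. Heat shock protein genes had a median of -0.23 over 23 genes, below all random lists, led by Hsph1 (-1.58), Hspa1a (-1.49) and Dnaja1 (-1.40). In the unfolded protein and integrated stress response list (28 genes, median -0.011, percentile 22.8) Chac1 (1.33), Trib3 (1.09) and Herpud1 (1.08) were at least 2-fold higher and Atf3 (-1.90) lower, and after normexp Chac1 alone stayed at least 2-fold higher. The circadian clock list had a median of 0.36 over 18 genes, above all random lists. Ciart (1.46) and the clock output gene Dbp (1.29) were at least 2-fold higher, and Nfil3 (-1.66) and Arntl (-1.30), which encodes BMAL1, at least 2-fold lower, with 1 in each direction left after normexp.

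Markers of several immune cells were lower. Lung markers and erythroid genes such as Alas2 (-2.97) and Hbb-bt (-2.84) were lower in the same heart. Whether the heart tissue itself held fewer immune cells therefore cannot be told from these lists. All but 1 of 25 macrophage markers had a ratio below 0, with a median of -0.70, below all random lists, and 9 were at least 2-fold lower, among them Ccr2 (-1.40), Adgre1 (-1.31), Cx3cr1 (-1.29) and Aif1 (-1.26). After normexp 3 macrophage markers were at least 2-fold lower and with the stricter filter 4, while the median was -0.64 in both. Neutrophil markers had a median of -0.56 over 8 genes (percentile 0.050), and 8 more were above background in the control only. Their bounds ran from at least 30.0-fold lower for Retnlg to at least 1.02-fold for Mpo. With bounds included, 5 of 16 neutrophil markers were at least 2-fold lower. B and plasma cell markers had a median of -0.82 over 9 genes (percentile 0.020), T and NK cell markers one of -0.13 over 14 genes (percentile 12.4). Inflammatory cytokine and adhesion genes had a median of -0.30 over 33 genes (percentile 0.010), led by Ccl4 (-2.35) and Ccl3 (-2.23), with Tlr4 (1.68) in the other direction, and Il1b was at least 9.86-fold lower. The median of interferon-stimulated genes was 0.13 over 39 genes (percentile 97.4), with Ifi27l2a (-1.22) the sole one at least 2-fold different. Cell cycle genes had a median of 0.047 over 23 genes (percentile 68.5), with Mki67 (1.31) and Ube2c (-1.92) in opposite directions. With bounds included their median was -0.16 over 31 genes, and after normexp none was at least 2-fold different. After normexp the B cell median was 0.019, the neutrophil median -0.17 and the inflammatory median -0.12, and with a stricter filter on dim probes they were 0.23, 0.21 and 0.063, all above 0.

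Atrial markers had a median of -0.63 over 17 measured genes, below all random lists. Besides Sln, Myl7 and Myl4, Dkk3 (-2.93) and Hamp (-2.52) were lower, and Fgf12 was above background in the control only, at least 14.6-fold lower. Tbx5 (0.17), Nr2f2 (0.12) and Pam (0.023) were near equal. All 12 lung markers that were above background in the control were lower in the WRN-K577M heart, 7 of them at least 2-fold with bounds included. Of the 12 markers, 8 were not well above background in the WRN-K577M heart. The median was -0.65 over the 4 measured on both (percentile 0.27) and -3.23 with the others at their bounds. Adipocyte markers had a median of -0.74 over 23 genes, below all random lists, with Adipoq (-3.31), Cidec (-3.16) and Pck1 (-2.81) beside Car3, while Fabp4 (0.53), Plin4 (0.53) and Pparg (0.29) were not lower. Erythroid markers had a median of -0.88 over 19 genes, below all random lists, with Alas2 (-2.97) and the beta-globin gene Hbb-bt (-2.84) among the lower ones. With the stricter filter on dim probes the adipocyte median was 0.031 and the atrial one -0.17. That filter leaves out genes dim on either array. Sln and Adipoq, with levels of -3.27 and -2.62 in the WRN-K577M heart, drop out by its design, so these moves do not show that the differences rest on dim genes.

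**Figure D3:**
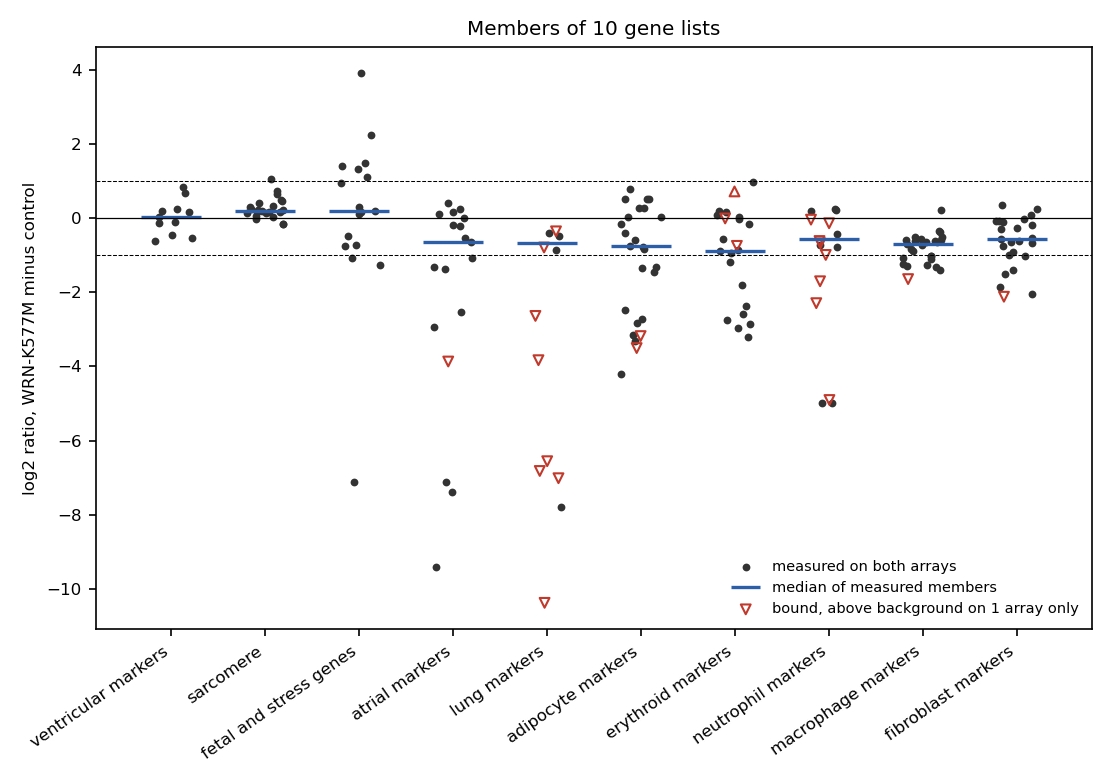
Log2 ratio (y axis, WRN-K577M minus control) of each member of 10 gene lists. Filled points are genes measured on both arrays, open triangles are bounds for genes above background on 1 array only, blue lines are medians of the measured members and dashed lines mark a 2-fold difference. Among members measured on both arrays, atrial ones reach -9.41 (Sln) and lung ones -7.78 (Scgb1a1), the bound of Sftpc lies lower still, and the 11 ventricular markers lie within 2-fold.

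Nerve and Schwann cell markers had a median of -0.31 over 18 genes (percentile 0.42), led by Dbh, dopamine beta-hydroxylase of noradrenergic cells (-2.73), and Prx (-1.44). Lists of the other cell types lay inside the central 95%. Endothelial markers had a median of -0.053 over 22 genes (percentile 13.7), led by Cldn5 (-0.99), smooth muscle and pericyte markers 0.048 over 19 genes (percentile 60.6), skeletal muscle markers -0.055 over 17 genes (percentile 17.6), epicardial and mesothelial markers 0.012 over 15 genes (percentile 56.4) and thymus markers -0.086 over 8 genes (percentile 17.5). Nuclear long non-coding RNAs had a median of 0.019 over 4 genes (percentile 45.6), with Neat1 (1.02) and Malat1 (-0.61) apart. Housekeeping genes had a median of 0.052 over 17 genes (percentile 32.2), with Tfrc, the transferrin receptor (-3.03), the sole one at least 2-fold different.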

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

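Probes without a gene name here enter none of the comparisons above. Of the 10264 such probes well above background on both arrays, 279 had a signal at least 2-fold higher in the WRN-K577M heart than in the control, and 140 at least 2-fold lower. Named genes split the other way, 271 higher and 484 lower. The unnamed probes were dimmer, with a median mean level of -1.61 against 0.72 for the named genes, and the 279 higher ones had a median of -2.49. Each named gene took its brightest probe, which raises the named level. In the dimmest tercile of measured named genes, 125 were at least 2-fold higher and 267 lower. Without a filter, which lets in named genes not well above background, the counts were 1240 higher and 1080 lower. The tercile was not matched to the level of the unnamed probes, so whether equally dim named genes split as those probes did is open. After normexp, which adds a constant to every signal, 48 unnamed probes were at least 2-fold higher and 73 lower. That alternative also changed the background method and the input signal, and no explanation of the split was tested.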

How the results depend on the processing

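The added filter on the mean level and the counts without other-tissue lists were chosen after seeing the data, and the other alternatives before. No named gene with a ratio of at least 2-fold turned its sign under any alternative: over all named genes, 1372 values moved by less than the spot error of 0.13 and 129 by more. No scaling moved the median of all genes by more than 0.051. Higher genes were 35.9% of those at least 2-fold different, between 29.4% and 36.9% under normexp and the other scalings, 53.4% without a filter and 46.6% with the stricter one. Of the 271 higher and 484 lower genes, 227 and 484 remained with cyclic loess, and 115 and 193 with normexp. Of the 18 low lists, between 15 and 18 remained low under the alternatives, except for 10 with the stricter filter, and the 3 high lists remained high under all. Without members of other-tissue and stromal lists, 269 genes were at least 2-fold higher and 422 lower. The number of arrays limits all values, and signal over background limits dim genes most.

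The counts were 271 higher and 484 lower at 2-fold, 946 and 1282 at 1.5-fold, 63 and 154 at 3-fold, 115 and 197 with normexp, 1240 and 1080 without a filter, 116 and 133 with the stricter filter and 106 and 119 with the filter on mean level. Both filters leave fewer genes. Normexp changed the background method, the offset and the input signal together, and which of these moved the counts was not tested. Bounds of at least 2-fold numbered 208, and 20 with normexp. The SD of the log2 ratio was 0.52, and 0.39 with normexp, 0.70 without a filter and 0.42 with the stricter one. The list medians that follow are those that moved by more than the SD of random lists, with the ventricular median under the stricter filter added, and smaller turns of sign of lists near 0 are left out. For these the cause was not tested, except that both filters leave fewer members.

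With normexp the medians were -0.033 for oxidative phosphorylation, 0.019 for B cell, 0.055 for T and NK cell, 0.089 for thymus and -0.090 for ventricular genes, all with the sign turned, and -0.24 for senescence, -0.31 for heat shock, -0.66 for immediate-early, -0.12 for inflammatory, -0.17 for neutrophil, -0.41 for adipocyte, -0.20 for nerve and 0.21 for ribosomal genes. With quantile normalization oxidative phosphorylation turned to -0.060 and housekeeping genes to -0.049, and others were 0.017 for sarcomere, 0.12 for fatty acid oxidation, -0.23 for glycolysis, 0.16 for Nrf2, -0.33 for heat shock and 0.17 for ribosomal genes. With cyclic loess oxidative phosphorylation turned to -0.088, ventricular genes to -0.081 and housekeeping genes to -0.074, and others were -0.11 for hypertrophic, 0.044 for sarcomere, 0.098 for fatty acid oxidation, -0.27 for glycolysis, 0.13 for Nrf2, -0.37 for heat shock and 0.13 for ribosomal genes. Oxidative phosphorylation was 0.013 with the median of all probes and 0.0045 with the deposited matrix, which gave 0.21 for ribosomal genes.

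Without a filter cell cycle (-0.16) and skeletal muscle genes (0.14) turned sign, and others were -0.83 for neutrophil, -0.15 for nerve, -2.86 for lung and 0.46 for nuclear RNA genes. The stricter filter leaves out genes dim on either array, those far lower on the WRN-K577M array among them, so its moves are partly built in. With it, 4 lists that lay below the random lists turned sign: inflammatory (0.063), B cell (0.23), neutrophil (0.21) and adipocyte genes (0.031). So did unfolded protein (0.11), ventricular (-0.031), epicardial (-0.26), thymus (0.18) and nuclear RNA genes (-0.52), which lay inside them. Others were -0.13 for senescence, -0.31 for immediate-early, 0.35 for cell cycle, -0.27 for skeletal muscle and -0.17 for atrial genes. With the filter on mean level, neutrophil (0.21) and adipocyte genes (0.031) turned sign, and others were -0.13 for senescence, -0.53 for immediate-early, -0.019 for inflammatory and -0.79 for atrial genes. No paired analysis was possible because each group holds 1 sample and no test was made.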

Other observations

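The genes of this paragraph were chosen after their values were seen. Single genes outside the lists above were higher in the WRN-K577M heart, and how other genes of their pathways stood was not counted: Hbegf, a ligand of the EGF receptor (log2 ratio 2.34), Dusp4 (1.93) and Etv5 (1.87), which ERK signalling is known to induce, and Tnfrsf12a, the receptor of TWEAK (1.67). The immediate-early list had a median of -0.81, with 10 of 26 genes at least 2-fold lower and 2 at least 2-fold higher. Dusp4 and Etv5 alone therefore do not show the state of ERK signalling. Among glutathione transferases, Gm10639 (2.13), Gm3776 (2.04) and Gsta2 (1.87), near-identical copies that were not told apart here, were higher. Apln, apelin, and its receptor gene Aplnr were lower together, with ratios of -3.07 and -2.57. Cftr (-3.27), Aqp5 (-3.27) and Scnn1a (-2.54), which airway epithelium is known to express, were lower, and so were Chil3 (-2.92), Ear2 (-2.31), Ear1 (-2.18) and Retnla (-1.93), which alveolar macrophages and eosinophils are known to express.

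All tests of the next 3 paragraphs were chosen after their results were seen. Lung genes and many atrial and adipocyte genes were lower in the WRN-K577M heart. Of the measured members, 5 of 17 atrial and 8 of 23 adipocyte markers lay above 0. With the stricter filter, which leaves out genes dim on either array, the atrial median was -0.17 and the adipocyte one 0.031. The median of the atrial genes nearest to 0 under 5 other scalings was -0.63, where the SD of random lists was 0.097. No scaling moved the median of all genes by more than 0.051, so this comparison could not have brought the atrial median to 0. It does not test the scaling between arrays, and shows only that the scalings differ little beside the atrial median. A candidate explanation is that the pieces of tissue differed, with a larger share of lung, fat and atrium in the control sample. Scgb1a1 was well above background in the WRN-K577M heart too, at a level of -2.02, so absence of lung there is not shown. All 12 lung markers above background on either array were lower, 7 of them at least 2-fold with bounds included. At 2-fold, 9 of 18 atrial markers and 11 of 25 adipocyte markers were lower with bounds included. For the atrial and adipocyte lists, random lists of matched control level reached 3 at their upper limit. These counts restate the pattern and do not favour an explanation. For the atrial and adipocyte genes, pieces of tissue and a genotype acting on the same cells cannot be told apart. There was 1 sample per genotype and no record of the dissection, and 8 of 17 measured atrial genes were at least 2-fold lower. For the lung genes, the heart cells of the control would have to make surfactant. Sftpc, made by lung epithelium, had a level of 5.96 in the control, Sftpd 2.60 and Sftpb 2.40. Of the 12 lung markers, 8 were above background in the control only. For the lung genes these levels argue against a genotype acting on the same cells.

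In the second pattern 6 of 17 fetal and stress genes of cardiomyocytes were at least 2-fold higher, the lowest of them by 1.12, and 3 (Myl4, Cnn1 and Nppa) were at least 2-fold lower, with a list median of 0.20 inside the random lists (percentile 93.7). A larger share of ventricular muscle in the WRN-K577M sample would raise ventricular markers as a set. Their median was 0.048 (percentile 37.2) and their upper quartile 0.22, which argues against such a share as the source of the 6 higher genes. The 6 were picked for a ratio of at least 1, so a gap between them and the markers is partly built in. The markers do not show which part of the ventricle was taken. Skeletal muscle in that sample is a possible source of Myh7. The 8 brighter skeletal muscle markers had a median of -0.27, the highest of them 0.91. All 17 measured markers had a median of -0.055 and an upper quartile of 0.54, with 8 above 0. Brighter markers such as Myl1 and Tnnt1 had levels of 4.82 and 3.95 in the control, so a small share of skeletal muscle would hardly raise them. These values do not exclude such a share. What also stays open is the genotype of the animal, which cannot be told apart from any other difference between the 2 samples. A genotype effect remains a hypothesis for the 6 higher stress genes.

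In the third pattern, clock genes differed in opposite directions: the median of 12 genes of the Dbp arm was 0.58 and that of 3 genes of the Arntl arm was -1.30. The median of the Arntl arm is the ratio of Arntl itself. Nfil3 (-1.66) was at least 2-fold lower too, and the remaining gene of that arm was not. The difference of 1.88 between the medians of the arms lay at percentile 99.99 of level-matched random gene sets, which restates the pattern. Hearts collected at different phases of the clock could give it. The hour of collection is not given in the sources used here. A genotype acting on the clock, with 4 of 18 clock genes at least 2-fold different, could give it too, and these cannot be told apart with 1 sample per genotype.

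A passenger segment or altered region in the transgenic line may show as neighbouring genes that differ together, and the tests of pairs and of single chromosomes were chosen before their results were seen, that of the longest run after. Over 13112 pairs of neighbouring measured genes whose names do not share a stem, 32 were at least 2-fold different in the same direction, against a median of 20 and an upper limit of 29.0 in 10000 shuffles of the genes. No chromosome stood apart: the highest percent of genes at least 2-fold different was 6.68, on chromosome 9, where shuffles reached a median of 7.06. The longest run held 4 genes on chromosome 2, Slc2a6 (-1.74), Adamtsl2 (-1.45), Fam163b and Dbh (-2.73), and 16 of 1000 shuffles held a run as long. Slc2a6 and Fam163b were dim, and the genes on either side, Cacfd1 (-0.070) and Sardh (-0.50), lay within 2-fold. Neighbours that the same cell type expresses give such pairs too, as Fcrls and Cd5l of macrophages may (-1.15 and -1.53), and the pair of Gm10639 and Gsta2, near-identical copies, is counted among the 32, so the excess alone does not show an altered segment.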
